A study of Mus musculus with 5 samples.

How the data were processed

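The series measured messenger RNA in single γδ T cells of C57BL/6 mice sorted by flow cytometry for the Vγ4 or the Vγ6 T cell receptor chain. The 5 libraries were made with the Chromium 3' v2 droplet kit, in which each transcript carries a unique molecular identifier (UMI). Mice were 8 weeks old, and 8 to 10 weeks for the pooled library. Per the labels, ear skin was digested with collagenase for 75 minutes at 37 °C. CD4 and CD8 cells of the thymus were lysed with antibody and complement for 30 minutes at 37 °C, and no incubation was stated for the lymph nodes. Tissue and preparation therefore differed together.

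For each library the deposited matrix held raw UMI counts of 27998 genes per cell barcode, with no normalization. The authors' processing notes name Cell Ranger 2.0, Seurat 2.3 and the mouse genome build mm10, without saying what each was used for. The authors also deposited 2 tables for 8 Vγ6 cell clusters. The first gave mean expression of 10721 genes in another unit, normalized so that each column sums to 10000. The second listed 26092 marker results. Its natural log fold changes of a cluster against other cells were computed by the authors before deposit and used as deposited, and its p-values were over cells. The authors' marker table held only p-values below 0.01, the highest being 0.00999. How these clusters were made was not stated, and the map from their cells to the matrices was not analysed here.

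Barcodes with at least 200 genes detected and at most 10% of UMIs from mitochondrial genes were kept. No doublets and no other cell types were removed in the main values. UMIs of the kept cells were summed per library and given as CPM, a gene's share of that sum in parts per 1e6. Kept cells and their summed UMIs numbered 1178 and 1933221 in skin Vγ4, 687 and 793463 in skin Vγ6, 1458 and 4210564 in pLN Vγ6, 2517 and 6607432 in thymus Vγ6, and 2006 and 2960908 in the pooled Vγ6 library. A count of 0 was bounded by 3 counts of the library total.

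Each group had 1 library, so no test between conditions was possible and cells were not used as replicates. Ratios of CPM carry an exact conditional binomial 95% interval, printed in parentheses after each ratio. CPM and list levels have exact Poisson intervals, and shares of cells exact Clopper-Pearson intervals. All intervals cover counting error only, not differences between animals, preparations or runs. A gene was called higher or lower when the ratio was at least 2-fold, the interval excluded 1, and the higher library had at least 20 CPM. These calls describe the libraries, not the tissues in general.

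The 4 comparisons were skin Vγ6 against pLN Vγ6, thymus Vγ6 against pLN Vγ6, skin Vγ6 against thymus Vγ6, and skin Vγ4 against skin Vγ6. Named genes were the 12 with the highest and the 12 with the lowest ratio, ranked by the interval bound nearest to 1. They needed a UMI in at least 20% of the cells and at least 100 CPM in the higher library. Mitochondrial and ribosomal protein genes and markers of non-T cell types were left out of this ranking. A fixed set of γδ T cell genes was added, some of which are not reported here, with the members of each gene list that changed most. That number was set to 4 per list after the alternatives had been seen.

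The 16 gene lists were fixed before the data were examined. They covered the IL-17 programme, immediate early genes, heat shock genes, NF-κB targets, activation and checkpoint genes, tissue residency, circulation and naive-type genes, cytotoxic and type 1 genes, cell cycle, type I interferon, Bcl2 family and survival, glycolysis and hypoxia, lipid handling, chemokine receptors, thymocyte maturation and the T cell receptor. The Bcl2 family and survival list, called the survival list below, mixes protective genes with genes that promote cell death, such as Bcl2l11 and Bak1. Its counts and medians are therefore no measure of survival. A member counted as measured with at least 20 CPM in either library. The median log2 ratio, with a pseudocount of 1 CPM, was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes the libraries and is not a test. Some genes belong to several lists, such as Cd69, Bhlhe40, Xcl1 and Satb1, so the lists are not separate evidence. Receptor segment genes such as Trdc and the Tcrg genes have no place in the matrices and are not analysed here.

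Each library was clustered alone in scanpy 1.11.5 (counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5, igraph 0.11.9). A cluster took the name of another cell type when at least 2 markers of its fixed list were among the 10 leading genes and at least 3 were detected in 10% of the cells at 2-fold over the other cells. Otherwise it counted as T cells if at least 3 γδ T17 markers were detected. These naming limits were refined after the clusters had been seen. The pooled cluster that took the dendritic name is called myeloid-led, since 8 macrophage and 4 dendritic markers were raised in it. Marker lists covered γδ T17, type 1 or cytotoxic, alpha beta T or thymocyte, regulatory T, innate lymphoid, B, dendritic, macrophage, neutrophil, mast, keratinocyte, fibroblast, endothelial, melanocyte, erythroid and cycling cells. For shares of cells with a UMI, every cell was thinned to 800 UMIs and shallower cells were left out. Mixing weights of the pooled library were fitted by non-negative least squares on the 3 single-tissue Vγ6 libraries.

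Alternatives fixed in advance were no or a stricter cell filter, T cell clusters only, doublet calls left out, TMM factors (edgeR 4.0.16) and median-of-ratios factors (DESeq2 1.42.0, R 4.3.3), the mean over cells, thinning, and mitochondrial, ribosomal and stress genes out of the total. Others were no or a 100 CPM minimum, a pseudocount of 10 CPM and resolution 1.0. Another 5 were added after the data had been seen: barcodes with part of the template-switch oligo left out, only the thymus cluster led by IL-17-type genes, dividing clusters left out by leading genes or by a marker rule, and thymus-like skin Vγ4 cells left out. By leading genes they were those with the cycling name and, in pLN, 3 clusters of 15.3%, 9.19% and 7.89% of the cells. These 3 had 1, 10 and 1 of 10 cycling markers raised and held 17.0%, 15.1% and 27.2% of the pLN UMIs. This alternative therefore left out more cells in pLN than elsewhere, also from clusters with few cycling markers raised. The marker rule, added later for this reason, left out every cluster with at least 5 of 10 cycling markers raised: 1 in skin Vγ4, skin Vγ6 and pLN and 2 in thymus. Coordinates are those of GRCm38, joined by Ensembl identifier. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

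The size rule, intervals, list percentiles and mixing weights were tested on simulated data of the same depth. Simulated 2.5-fold changes were called for 84.0% to 98% of genes and 4-fold changes for 100%, and at most 34 of 4551 unchanged genes were called. Simulated mixing shares of 20, 50 and 30% came back as 19.98, 49.95 and 30.1%. The simulated counts were Poisson draws without differences between animals, preparations or runs. The simulated pool was an exact mixture of the fitted profiles, so these results cover counting error only.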

Results

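The 5 sorted γδ T cell libraries were each the only one of their group: Vγ4 cells of ear skin, Vγ6 cells of ear skin, peripheral lymph node (pLN) and thymus, and a pool of Vγ6 cells from these tissues without a map from cells to tissues. Kept cells held 793463 UMIs in skin Vγ6, the shallowest library, and 6607432 in thymus Vγ6, the deepest. Median UMIs per cell were 1455 in skin Vγ4, 1059 in skin Vγ6, 1775.5 in pLN Vγ6, 2156 in thymus Vγ6 and 1303.5 in the pool. Median genes per cell were 725, 588, 964, 1054 and 763 in the same order. There were no replicates, so no difference could be set against the spread between animals.

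The comparison of skin with pLN asked how cells of the same sorted subset differ between a barrier tissue and lymph node. IL-17-producing γδ T cells of skin defend the barrier and recruit neutrophils, whereas those of lymph node can recirculate and divide. Genes that open or close these programmes were therefore read together. The skin library held far more transcript of IL-17-family cytokines. Il17f, a cytokine that recruits neutrophils (ENSMUSG00000041872, chromosome 1, 20777146 to 20790617), was at 1009.5 CPM in skin and at 4 UMIs in pLN, 1063-fold (413 to 3909.6) higher. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) was 69.1-fold (49.9 to 98.4) higher at 640.2 against 9.26 CPM. Within the pool, cells fitting the skin profile best held Il17a at 430 CPM and those fitting pLN best at 174, a far smaller difference. Il17f was at 802 and 18.2 CPM in the same cells. The scavenger receptor gene Cd163l1, typical of Vγ6 cells, was level at 768 against 753 CPM, a ratio of 1.02 (0.933 to 1.11). Across 5770 genes with at least 20 CPM, 922 were higher and 1756 lower in skin.

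Activation-type genes were higher in skin across several lists. All 15 NF-κB targets were higher, with a median log2 ratio of 4.20, among them Rel at 51.7-fold, Nfkbiz at 40.5-fold and Relb at 25.5-fold. Of 23 immediate early genes, 22 were higher (median 2.75), including Nr4a1 at 325-fold (148 to 893), Gadd45b at 84.7-fold (67.9 to 107), Nr4a3 at 95.5-fold and Atf3 at 156-fold. Junb was 15.8-fold and Fos 6.58-fold higher. Of 18 activation and checkpoint genes, 17 were higher (median 3.66, or 2.78 with no CPM minimum). Areg, a growth factor linked to tissue repair, had 0 UMIs in pLN and was at least 814-fold higher, Tnfsf11 was 83.6-fold, Tnfrsf9 42.8-fold and Vps37b 43.9-fold higher. The checkpoint gene Pdcd1 was 5.90-fold and the costimulatory gene Icos 2.78-fold higher. Heat shock genes were 6 higher and 1 lower of 12 (median 1.14), led by Hspa1a at 30.5-fold. The median mitochondrial share of kept cells was 5.97% in skin Vγ6 and 3.88% in pLN. Over the mitochondrial limit were 120 of 812 skin Vγ6 and 2 of 1461 pLN barcodes. Keratinocyte markers stood beside these lists at 271 CPM in skin Vγ6 and 66.3 CPM in pLN. Of these markers, Sfn alone was at 226 and 15.4 CPM, and Krt14 at 1.26 and 0.475 CPM.

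Other genes with the highest ratios were the neutrophil-attracting chemokine Cxcl2 at 1048-fold (288 to 8684), from 2 UMIs in pLN, Sdc4 at 43.2-fold, Sytl3 at 62.5-fold and the cAMP-responsive regulator Crem (ENSMUSG00000063889, chromosome 18, 3266048 to 3337748) at 37.8-fold (31.5 to 45.7). Tissue residency genes were 7 higher and 1 lower of 10 (median 2.69, or 1.48 with no CPM minimum), with Bhlhe40 39.4-fold, Rgs2 10.6-fold and Cd69 6.60-fold higher. Of the higher ones, Bhlhe40 is also in the activation list, Cd69 in the immediate early list and Xcl1 in the cytotoxic list. The skin-homing receptor gene Ccr10 went the other way, 9.80-fold lower in skin, while Itgae and Cxcr6 had ratios of 1.52 (1.08 to 2.11) and 1.24 (1.18 to 1.30). Bcl2 family and survival genes were 7 higher and 3 lower of 13 (median 1.44). Of the higher ones, Bcl2l11 and Pmaip1 promote cell death, as do the lower ones, Bak1, Bid and Bad. Bcl2a1b was at 3742 against 261 CPM, 14.3-fold (13.4 to 15.4) higher, and Bcl2l1 was 10.7-fold higher. Bcl2a1a, Bcl2a1b and Bcl2a1d are near-identical paralogs, so how their reads divide is uncertain. Bcl2 itself had a ratio of 1.75 (1.11 to 2.69).

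Within the IL-17 programme, 6 of 24 measured genes were higher and 5 lower, and the median of 0.14 was 0.45 with TMM but turned to -0.14 with the mean over cells and -0.33 with dividing clusters left out by leading genes, against 0.22 by the marker rule. Il22 was 128-fold and Rora 5.78-fold higher, while Ccr6 had a ratio of 0.555 (0.367 to 0.809), and 5830411N06Rik stayed at 2 and 6 UMIs. Cytotoxic genes were 7 higher of 9 (median 1.86, or 0.60 with no CPM minimum), with Il2rb 8.36-fold and Gzmb 5.68-fold higher. Xcl1 was 41.1-fold and Klrd1 4.36-fold higher, but with T cell clusters only these became 0.44 and -0.36 in log2. Hilpda at 27.9-fold and Hk2 at 22.8-fold were among 4 higher and 3 lower of 15 glycolysis and hypoxia genes (median 0.07). Chemokine receptors were 3 higher and 1 lower of 9 (median 0.61), and lipid handling genes 2 higher and 2 lower of 7 (median -0.52, but 0.61 with the stricter filter), where after thinning the calls for Acsl4 (0.55), Abcg1 (0.38) and Fabp5 (-0.62) ended. Thymocyte maturation genes were 2 higher of 5, with a median of 0.79 that turned to -0.18 after thinning and -0.67 with no CPM minimum.

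Most genes of the cell cycle and interferon lists were lower in skin. Of 22 cell cycle genes 20 were lower and none higher (median -2.90, or -1.83 with dividing clusters left out by leading genes and -3.54 by the marker rule), including Rrm2 at 14.1-fold, Ccnb1 at 20.2-fold, Tyms at 17.3-fold and Ube2c at 14.4-fold. Among the genes with the lowest ratios were 2810417H13Rik at 28.3-fold (21.3 to 38.6), the histone genes Hist1h1b at 37.5-fold and Hist1h1e at 22.2-fold, Tipin at 21.3-fold, Ms4a4b at 30.4-fold, Ms4a6b at 37.1-fold, AW112010 at 19.8-fold, Gm4955 at 25.5-fold, Psmb10 at 21.4-fold and Mrpl40 at 23.9-fold. Klf2, which drives exit from tissue, was at 45.4 against 753 CPM, 16.6-fold (11.96 to 23.7) lower (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656), and the egress receptor gene S1pr1 4.68-fold lower. The circulation list as a whole was 3 higher and 3 lower of 12, with Satb1 4.69-fold and Cd27 3.59-fold higher, and its median of 0.22 turned to -0.38 with the mean over cells and -0.50 with dividing clusters left out by leading genes, against 0.14 by the marker rule. Of 15 interferon genes 11 were lower and 1 higher (median -2.01), with Rtp4 at least 7.04-fold and Ifit1, from 1 UMI, 16.0-fold (2.80 to 640.0) lower. Of 5 T cell receptor complex genes 1 was lower (median -0.93), Cd3g at 2.03-fold. Dendritic markers were at 677 CPM in skin and 1453 in pLN, and cycling markers at 589 and 4195 CPM.

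The random-list percentile was 100 for the NF-κB, immediate early, activation, residency and survival lists, 99.99 for heat shock, 99.95 for cytotoxic, 97.16 for IL-17, 0 for cell cycle and 0.09 for interferon genes. The median log2 ratio of all genes was -0.38, against -0.08 with TMM and -0.08 with median-of-ratios factors, and the share of calls that were higher went from 34.4% to 50.5% and 50.8%. Under both factors and 2 other alternatives the call for Cd3g ended, and the Cd27 call ended after thinning (0.93).

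The comparison of thymus with pLN asked how the subset differs between its organ of origin and lymph node. Vγ6 cells mature in the thymus before birth, where a transcription factor such as Sox4 guides early T cells and Ccr9 guides homing. Cells that leave it settle in the periphery. The thymus library carried genes of developing and recirculating T cells and lower IL-17-type genes. Cd28, the costimulatory receptor (ENSMUSG00000026012, chromosome 1, 60716800 to 60773359), was at 234 against 2.14 CPM, 109-fold (57.5 to 239.8) higher. Sox4, a transcription factor of early T cells (ENSMUSG00000076431, chromosome 13, 28948919 to 28953713), was 58.8-fold (38.4 to 95.2) higher, and the granzyme gene Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981) 43.6-fold (34.3 to 56.4) higher at 694 against 15.9 CPM. Of 5703 genes, 673 were higher and 647 lower in thymus.

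Thymocyte maturation genes were 15 higher of 17 and none lower (median 4.02, or 2.57 with a pseudocount of 10 CPM), with Cd24a 73.2-fold (45.0 to 128) and Tox2 at least 55.0-fold higher. Circulation genes were 9 higher and 2 lower of 15 (median 2.04), among them Satb1 at 19.8-fold, Lef1 at 16.5-fold and Cd27 at 11.9-fold, while S1pr1 had a ratio of 1.87 (1.66 to 2.10). Cytotoxic genes were 7 higher and 1 lower of 10 (median 2.79, or 1.39 with no CPM minimum), with Ctsw 14.7-fold, Xcl1 28.8-fold and Nkg7 7.52-fold higher. Alpha beta T or thymocyte markers were at 159 CPM in thymus and 15.7 in pLN, and mast cell markers at 136 and 1.19 CPM. The mast cell list includes Cpa3, at 232 CPM in the largest thymus cluster, which counted as T cells. Other genes at the top were Nrgn at 125-fold, Gramd3 at 115-fold, Izumo1r at 74.4-fold, Plac8 at 47.1-fold, the thymic homing receptor gene Ccr9 at 42.1-fold and Ctla2a at 39.7-fold. Lck, a kinase of receptor signalling, was 17.5-fold higher, the 1 call of 6 T cell receptor genes (median 0.07, but -0.0845 with the mean over cells and -0.0755 after thinning).

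The IL-17 programme was 14 lower and 4 higher of 24 (median -1.37). Maf was 6.93-fold, Ccr6 6.93-fold and Cd163l1 2.65-fold (2.498 to 2.80) lower, whereas Il22 was 97.6-fold, 5830411N06Rik 22.9-fold and Il17a 2.91-fold (2.05 to 4.23) higher. Il17f stayed below 20 CPM in both, at 10.7 CPM in thymus. Chemokine receptors were 2 higher and 4 lower of 7 (median -1.77, or -0.71 with no CPM minimum), with Cxcr6 5.77-fold (5.51 to 6.04) lower and Ccr7 7.48-fold higher. Residency genes were 3 higher and 2 lower of 9, with a median of 0.37 that turned to -0.06 with TMM and -0.11 with median-of-ratios factors, and also below 0 under 4 of the cell choices, down to -0.15 with doublet calls left out. Its member Rgs2 was 17.1-fold higher, while Cd69 and Itgae had ratios of 0.628 (0.559 to 0.704) and 0.540 (0.428 to 0.681). Further genes with the lowest ratios were Bcl2a1a at 11.5-fold, 1500009L16Rik at 9.10-fold, Cd48 at 7.85-fold, Acsbg1 at 6.86-fold, Itgb1 at 6.43-fold, Gm42418 at 6.47-fold, Ltb4r1 at 6.16-fold, Hist1h1b at 6.68-fold and Hist1h1e at 6.76-fold. Cell cycle genes were 13 lower of 22 (median -1.26), with Mki67 4.61-fold lower. With dividing clusters left out this median was -0.09 by leading genes but -2.29 by the marker rule. By leading genes the Hist1h1b call ended (-0.33), and Ccna2 and Rrm2 changed direction.

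Activation-type lists were higher in thymus as in skin. Activation and checkpoint genes were 13 higher and 2 lower of 17 (median 2.54), including Vps37b at 44.9-fold (37.1 to 54.9), Tnfsf11 at 22.1-fold, Pdcd1 at 5.15-fold and Areg, higher by at least 41.0-fold. Icos had a ratio of 1.48 (1.35 to 1.63). Immediate early genes were 12 higher of 21 (median 1.51), with Nr4a1 30.8-fold, Fosl2 22.6-fold, Junb 5.16-fold and Fos 2.90-fold higher. Heat shock genes were 9 higher of 13 (median 1.23), led by Hspb1 at 55.4-fold and Hspa1a at 19.2-fold, and NF-κB targets 7 higher of 11 (median 1.68), led by Tnfaip3 at 9.86-fold. Crem was 40.2-fold (33.9 to 48.0) higher at 1278 against 31.8 CPM. Interferon genes were 6 higher of 16 (median 0.66), among them Ifi27l2a at 8.58-fold and Irf7 at 5.23-fold. With dividing clusters left out this median was 0.03 by leading genes and 0.94 by the marker rule. Bcl2 family and survival genes were 3 higher and 4 lower of 11 (median -0.50). The death-promoting Bcl2l11 was at 304 against 15.2 CPM, Bcl2 was 3.42-fold higher and Bcl2a1b 2.02-fold lower. Glycolysis genes were 3 higher of 14 (median 0.00) and lipid handling genes 3 higher and 1 lower of 9 (median 0.74).

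Of the thymus cells, 25.8% fell in the cluster led by IL-17-type genes, and with this cluster alone the IL-17 list median for thymus over pLN turned to 0.46, the chemokine receptor median to -0.34, the circulation median to 0.64, the thymocyte and cytotoxic medians to 2.12 and 1.96, the survival median to 0.0256, Cd163l1 to 0.49, Bcl2 to -0.29 and Bcl2a1b to 0.36, while the calls for Ccr6 (-0.80), Cxcr6 (-0.74), Ltb4r1 (-0.71) and Nkg7 (0.93) ended. The Bcl2a1b call also ended under 5 other alternatives, among them TMM (-0.93) and the marker rule (-0.74), and those for Bcl2 (0.62) and Fos (0.98) with dividing clusters left out by leading genes. The random-list percentile was 100 for the thymocyte, circulation, cytotoxic, activation, immediate early, heat shock and NF-κB lists and 0 for the IL-17, chemokine receptor and cell cycle lists.

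**Figure D1:**
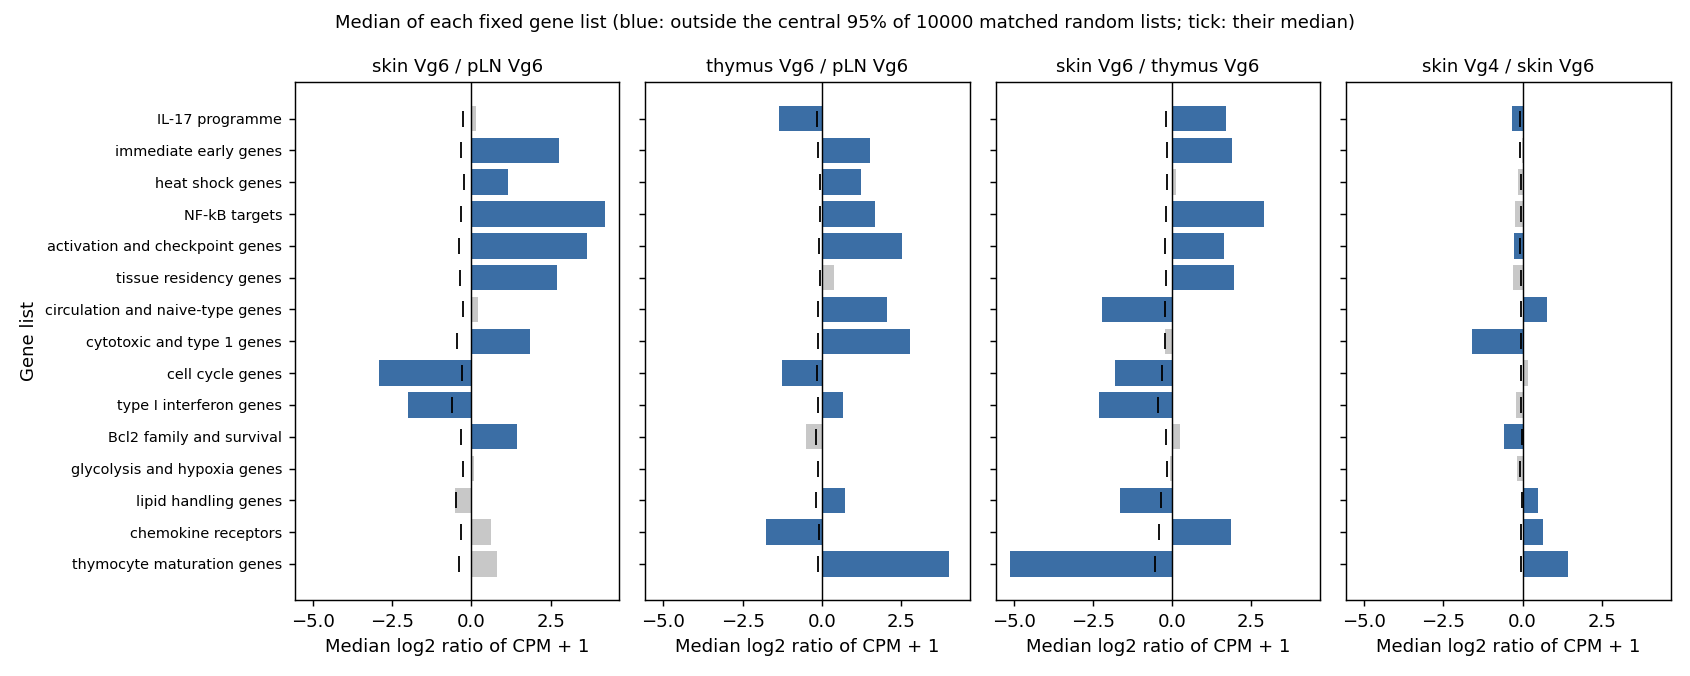
Median log2 ratio (horizontal axis) of 15 gene lists (vertical axis) in the 4 comparisons (panels), with the T cell receptor list not drawn. Blue bars lie outside the central 95% of 10000 matched random lists, grey bars inside it, and ticks mark the random median. Values were computed from summed UMI counts with a pseudocount of 1 CPM and 1 library per group. NF-κB targets sat at 4.20 for skin over pLN and 1.68 for thymus over pLN, and thymocyte maturation genes at 4.02 and -5.11 for thymus over pLN and skin over thymus. The residency median for thymus over pLN, cytotoxic and glycolysis medians for skin over thymus, and immediate early and interferon medians for skin Vγ4 over Vγ6 changed sign with another scaling.

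The comparison of skin with thymus asked how the subset differs between a barrier tissue and its organ of origin. Vγ6 cells mature in the thymus before birth, and the mice here were 8 weeks old. The thymus library can therefore not be read as the precursors of the skin cells. Skin held more Il17a, Il17f and activation-type transcript, thymus more developmental transcript, while Il22 did not pass the size rule. Il17a was at 640.2 against 26.9 CPM, 23.8-fold higher in skin, and Il17f 93.9-fold (73.6 to 122) higher. Within the pool, cells fitting skin best held Il17a at 430 CPM and those fitting thymus best at 232, a far smaller difference. Il17f was at 802 and 44.3 CPM in the same cells. Gzma was 275-fold (76.2 to 2274) lower in skin, from 2 UMIs, and Cd24a, a marker of immature T cells, 221-fold (39.6 to 8723) lower, from 1 UMI. Of 5656 genes, 773 were higher and 1385 lower in skin.

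The IL-17 programme was 14 higher and 1 lower of 24 (median 1.69), with Cd44 10.6-fold, Cd163l1 2.70-fold (2.46 to 2.96) and Ccr6 3.84-fold higher and 5830411N06Rik 12.97-fold (3.55 to 108) lower, from 2 UMIs. With the thymus cluster led by IL-17-type genes alone this median was -0.05, Cd163l1 turned to -0.46 and Ccr6 to -0.06, and the calls for Fos (0.16), Junb (0.60), Itgae (0.13), Nkg7 (-0.18) and 5830411N06Rik (-0.99) ended. After thinning those for Fos (0.99) and Itgae (0.91) ended too, that for Fos also with the stricter filter (0.94). NF-κB targets were 13 higher of 15 (median 2.89, or 2.01 with that thymus cluster alone), among them Tnf at 17.8-fold, Rel at 14.4-fold (12.7 to 16.3) and Icam1 at 11.5-fold. Immediate early genes were 19 higher of 23 (median 1.89, or 1.09 with that thymus cluster alone), including Gadd45b at 17.6-fold, Cd69 at 10.5-fold, Junb at 3.07-fold and Fos at 2.27-fold. Activation genes were 12 higher and 2 lower of 18 (median 1.63), with Il2ra 45.3-fold (34.4 to 60.3) and Areg 19.8-fold higher and Ctla4 at least 9.09-fold lower. Pdcd1 and Icos had ratios of 1.15 (1.01 to 1.30) and 1.88 (1.66 to 2.12). Heat shock genes were split, 2 higher and 4 lower of 13 (median 0.13, but -0.29 with that thymus cluster alone).

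Also higher in skin were Cxcl2 at 106-fold (73.6 to 158), Sdc4 at 77.4-fold, the convertase gene Furin at 46.6-fold (40.9 to 53.2), Anxa1 at 23.7-fold and the paralogs Bcl2a1a at 56.9-fold, Bcl2a1b at 29.0-fold and Bcl2a1d at 25.8-fold. Bcl2 family and survival genes as a list were 4 higher and 1 lower of 12 (median 0.25), the lower one being the death-promoting Bcl2l11. Bcl2 had a ratio of 0.512 (0.339 to 0.745). Residency genes were 6 higher of 9 (median 1.94, or 0.62 with no CPM minimum, 1.16 after thinning and 1.02 with that thymus cluster alone), with Cxcr6 7.14-fold, Rgs1 6.03-fold and Itgae 2.82-fold higher. Chemokine receptors were 6 higher and 2 lower of 9 (median 1.84, or 0.62 with no CPM minimum). Innate lymphoid markers, which include Areg and Rora, were at 1555 CPM in skin Vγ6, 298 in thymus and 205 in pLN. Regulatory T cell markers, which include Il2ra and Tnfrsf9, were at 1233, 966 and 359 CPM.

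Thymocyte maturation genes were 15 lower of 17 in skin, with a median of -5.11, or -3.07 with counts of 0 at the floor and -2.30 with a pseudocount of 10 CPM. Examples were Sox4 at 116-fold, from 2 UMIs and an interval of 32.2 to 962, and Ccr9, lower by at least 45.0-fold. Lef1, Itm2a and Cd28 also rested on 2 UMIs in skin and were 107-fold (29.7 to 887), 105-fold (29.1 to 869) and 92.8-fold (25.7 to 767) lower. Plac8 was 129-fold (50.2 to 472), Ms4a4b 74.0-fold, Gimap6 63.8-fold and Izumo1r at least 37.4-fold lower. Circulation genes were 11 lower and 2 higher of 15 (median -2.22, or -0.72 with that thymus cluster alone), with Klf2 10.4-fold and S1pr1 8.72-fold lower. Cell cycle genes were 18 lower of 22 (median -1.79), and Tyms was 10.7-fold lower, but with the thymus cluster led by IL-17-type genes alone the median was 0.01. Interferon genes were 16 lower of 17, with a median of -2.30 or -2.18 at the floor, with Ifi27l2a 34.2-fold and Rtp4 at least 27.0-fold lower. Lipid handling genes were 5 lower of 9 (median -1.65, or -0.53 with no CPM minimum and -0.62 with that cluster alone), with Acsl3 13.2-fold lower.

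T cell receptor genes were 3 lower of 6 (median -0.88), Lck by 24.9-fold. Cytotoxic genes went both ways, 3 higher and 4 lower of 11, with Klrk1 7.60-fold higher and Nkg7 4.49-fold lower. Their median of -0.21 was not stable: -1.002 with no CPM minimum, 1.05 with the stricter filter, 0.82 with that thymus cluster alone, 0.01 with TMM and 0.06 with median-of-ratios factors. Glycolysis genes were 3 higher and 2 lower of 15, and their median of -0.06 turned to 0.16 and 0.21. The median of all genes was -0.27, against -0.05 with TMM and 0.00 with median-of-ratios factors, and the share of calls that were higher went from 35.8% to 49.6% and 54.0%. The random-list percentile was 100 for the IL-17, NF-κB, immediate early, activation and residency lists and 0 for the thymocyte, circulation, cell cycle and interferon lists.

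**Figure D2:**
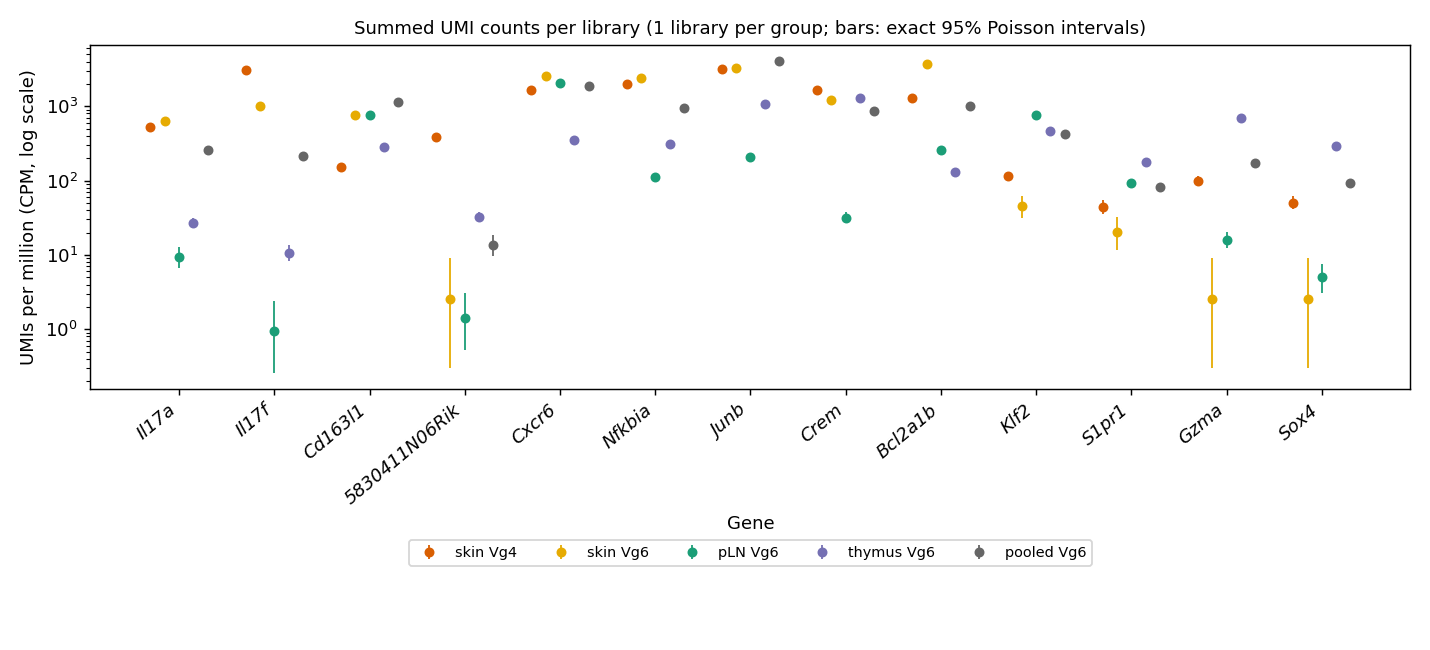
Summed UMI counts as CPM (vertical log axis) of 13 genes (horizontal axis) in the 5 libraries (colours), 1 library per group, with exact 95% Poisson intervals. Il17f stood at 3095 CPM in skin Vγ4, 1009.5 in skin Vγ6 and 10.7 in thymus Vγ6, and Crem at 31.8 CPM in pLN Vγ6 against 1278 in thymus Vγ6.

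The comparison of Vγ4 with Vγ6 cells of skin asked how these subsets differ within a tissue. Both make IL-17 cytokines and share the same environment, but they arise in separate waves and carry separate receptors. Scavenger receptors of the CD163 family are known to mark subsets of γδ T cells. The libraries were alike in most genes: of 4973, 212 were higher and 158 lower in Vγ4, and the correlation across genes was 0.891, with genes not being independent replicates. The scavenger receptor genes divided them. 5830411N06Rik (ENSMUSG00000054672, chromosome 7, 140247284 to 140300736) was at 385 against 2.52 CPM, 745 against 2 UMIs, 153-fold (42.2 to 1265) higher in Vγ4, and Cd163l1 (ENSMUSG00000025461, chromosome 7, 140218267 to 140231145) was 5.03-fold (4.37 to 5.80) lower. Il17f was 3.07-fold (2.85 to 3.30) higher in Vγ4 at 3095 against 1009.5 CPM, a call that ended with the stricter cell filter, which kept 249 and 142 cells (log2 ratio 0.42 in place of 1.62), while Il17a had a ratio of 0.831 (0.746 to 0.926).

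The IL-17 programme was 3 higher and 4 lower of 24 (median -0.33), with Il22 9.83-fold (6.54 to 15.2) and Zbtb16 6.23-fold lower in Vγ4 and Ccr6 2.01-fold higher. Other genes higher in Vγ4 were the tetraspanin gene Cd9 at 11.3-fold (7.61 to 17.6), Tnfrsf18 at 4.21-fold (3.17 to 5.70), Lgals3 at 2.69-fold, Satb1 at 2.73-fold, Hlf at 2.53-fold, Bcl2l11 at 2.48-fold, Klf4 at 2.21-fold and Ifngr1 at 2.18-fold. Lower in Vγ4 were Bcl2a1a at 8.83-fold (7.18 to 10.9), Fgl2 at 4.52-fold, Bcl2a1b at 2.88-fold (2.73 to 3.04), Ltb at 2.71-fold, Sepp1 at 2.59-fold, Bcl2a1d at 2.16-fold, Stx11 at 2.20-fold and Cxcl2 at 2.02-fold. The Cxcl2 call ended under 6 alternatives, down to -0.92 with TMM, and the Klf4 call with the stricter filter (0.80). Bcl2 family and survival genes as a list were 1 higher, the death-promoting Bcl2l11, and 3 lower of 12 (median -0.59). Bcl2 had a ratio of 1.15 (0.742 to 1.82). Gm42418 and Ramp3 ranked high and Gm10116 low, with ratios of 1.92 (1.59 to 2.33), 1.80 (1.66 to 1.96) and 0.505 (0.449 to 0.569) that did not reach 2-fold.

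The activation-type lists had few calls. Immediate early genes were 1 higher of 23 and their median was -0.02 (0.07 with TMM and -0.01 with median-of-ratios factors), with Fos, Junb and Cd69 at ratios of 1.38 (1.19 to 1.60), 0.952 (0.909 to 0.997) and 0.794 (0.726 to 0.868). None of 15 NF-κB targets passed the size rule (median -0.24), and 1 of 13 heat shock genes did (median -0.16). Activation genes were 2 higher and 4 lower of 17 (median -0.26), with Zeb2 8.69-fold, Csf2 7.92-fold and Pdcd1 3.03-fold lower and Icos at 0.663 (0.576 to 0.765). Residency genes were 1 higher and 2 lower of 10 (median -0.29), with Cxcr6 and Itgae at ratios of 0.651 (0.616 to 0.689) and 0.926 (0.651 to 1.33). With the stricter filter the NF-κB, activation and residency medians were -0.56, -0.63 and -0.85. None of 15 glycolysis genes (median -0.18) and of 5 T cell receptor genes (median -0.30) passed. Cell cycle genes were 2 higher of 15 (median 0.18), and 1 of 6 interferon genes was lower (median -0.22, 0.14 with TMM and 0.07 with median-of-ratios factors).

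Circulation genes were 4 higher and 1 lower of 13 (median 0.76), with Klf2 2.54-fold and S1pr1 2.18-fold higher. Chemokine receptors were 4 higher and 1 lower of 11 (median 0.64, but -0.0990 with no CPM minimum), with Ccr8 2.80-fold higher and Ccr2 3.41-fold lower. Thymocyte maturation genes were 5 higher of 9 (median 1.43), among them Sox4 at 20.1-fold (5.42 to 168). Beside them stood a cluster of 42 thymus-like skin Vγ4 cells, and without it this median was 0.53 and Gzma, 39.4-fold (10.8 to 328) higher, went from 5.30 to 1.24 in log2. Cytotoxic genes were 1 higher and 6 lower of 10 (median -1.60, but -0.77 with T cell clusters only and -0.33 with no CPM minimum), with Ccl5 at 1 against 183 UMIs, 446-fold (79.0 to 17706) lower. Xcl1 was 18.9-fold lower, but 0.72 in log2 with T cell clusters only, where the Klrd1 call also ended (-0.11). Lipid handling genes were 2 higher of 8 (median 0.48), led by Apoe at 111-fold (30.6 to 919), from 2 UMIs in Vγ6. In log2 Apoe went from 6.79 to 3.89 with T cell clusters only, since the 8 keratinocyte-named cells held it at 7766 CPM against 38.4 in the other skin Vγ4 cells. Beside Apoe, keratinocyte markers were at 1492 CPM in Vγ4 and 271 in Vγ6, neutrophil markers at 217 and 1.26, and dendritic markers at 71.9 and 677. Of the keratinocyte markers, Sfn alone was at 226 CPM in Vγ6. After thinning, the calls for Ccr6 (0.68) and S1pr1 (0.79) ended, Ccr6 also under 3 other alternatives and S1pr1 with the stricter filter (0.68). The share of calls that were higher was 57.3%, and 68.3% with TMM, 49.3% after thinning and 49.9% with the stricter filter. The random-list percentile was 100 for circulation, 99.98 for thymocyte and 99.94 for chemokine receptor genes, 0 for cytotoxic and survival genes and 0.07 for IL-17 genes.

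At 800 UMIs per cell, 57.8% (54.8 to 60.7) of skin Vγ4 and 15.5% (12.6 to 18.7) of skin Vγ6 cells had an Il17f UMI, against 0.0686% in pLN and 0.718% in thymus. Without thinning the skin shares were 67.8% and 16.7%, and thinning left out 39 skin Vγ4, 125 skin Vγ6, 0 pLN and 10 thymus cells. Cells of the myeloid-led cluster of the pool had 0 of 30 for Il17f and Il17a, which allows up to 11.6%, and before thinning 5.26% of them had Il17a. Shares below that could not be told apart from background in this way, and free RNA was not measured in the other libraries. In thymus both genes were uneven between clusters. Il17a was at 111 CPM in the cluster led by IL-17-type genes against 4.28 in the largest cluster, and Il17f at 44.3 against 2.14. The former cluster was chosen by such markers. Il17a UMIs were in 21.0% and 18.0% of skin Vγ4 and Vγ6 cells. Cd163l1 was in 51.4% of pLN and 46.1% of skin Vγ6 cells, and in 10.6% of skin Vγ4 and 18.6% of thymus cells. None of these shares passed the upper limit for the myeloid-led cells, 33.3% (17.3 to 52.8), so background could not be told apart for this gene. The median depth of those cells before thinning was 1799 UMIs. 5830411N06Rik was in 26.3% of skin Vγ4 and 0.356% of skin Vγ6 cells.

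Clustering showed how mixed each sort was. In thymus, 50.1% of cells formed a cluster with Gzma at 1093, Plac8 at 1054 and Sox4 at 469.9 CPM, and 25.8% the cluster led by IL-17-type genes, with Cd163l1 at 1055 and Il22 at 493 CPM. A further 4.65% took the cytotoxic name, with Ccl5 at 4221 CPM, and 3.58% the alpha beta or thymocyte name, with Dntt at 495 and Cd8b1 at 263 CPM. In pLN, 64.5% formed the largest cluster. Another, 7.89% of the cells, gave 27.2% of the UMIs at a median of 9962 UMIs per cell, with Batf3 at 242 and Fabp5 at 211 CPM. Skin Vγ4 held 0.679% keratinocyte-named cells, skin Vγ6 2.18% with the cytotoxic name, and 0 of 1458 pLN cells lay outside the T cell names, with an upper bound of 0.253%. These shares depended on the resolution: at 1.0 they were 0% of skin Vγ4, 4.80% of skin Vγ6, 15.9% of thymus and 7.54% of pLN cells, the last 110 cells led by Ccl5 and the antigen presentation genes H2-Aa and Cd74. Clusters with at least 9 cycling markers raised were 4.75% of skin Vγ4, 4.08% of skin Vγ6, 9.19% of pLN and 9.10% of thymus cells, without the alpha beta or thymocyte cluster, where 7 cycling markers were raised, and a pLN cluster (15.3%) with Ccnb2 and Cenpa among its leading genes. Across the skin Vγ6, pLN and thymus libraries, B cell markers were at 2.52, 119 and 37.5 CPM, macrophage markers at 27.7, 49.6 and 5.30, and endothelial markers at 15.1, 46.1 and 51.6. Erythroid markers were at 115, 36.1 and 1.97 CPM. Fibroblast and melanocyte markers reached 1.69 and 0.675 CPM at most, in the pool. γδ T17 markers were at 7079 CPM in skin Vγ4, 6082 in skin Vγ6, 6941 in pLN, 4906 in thymus and 8237 in the pool, and cytotoxic markers at 747, 1138, 358, 1725 and 1254.

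**Figure D3:**
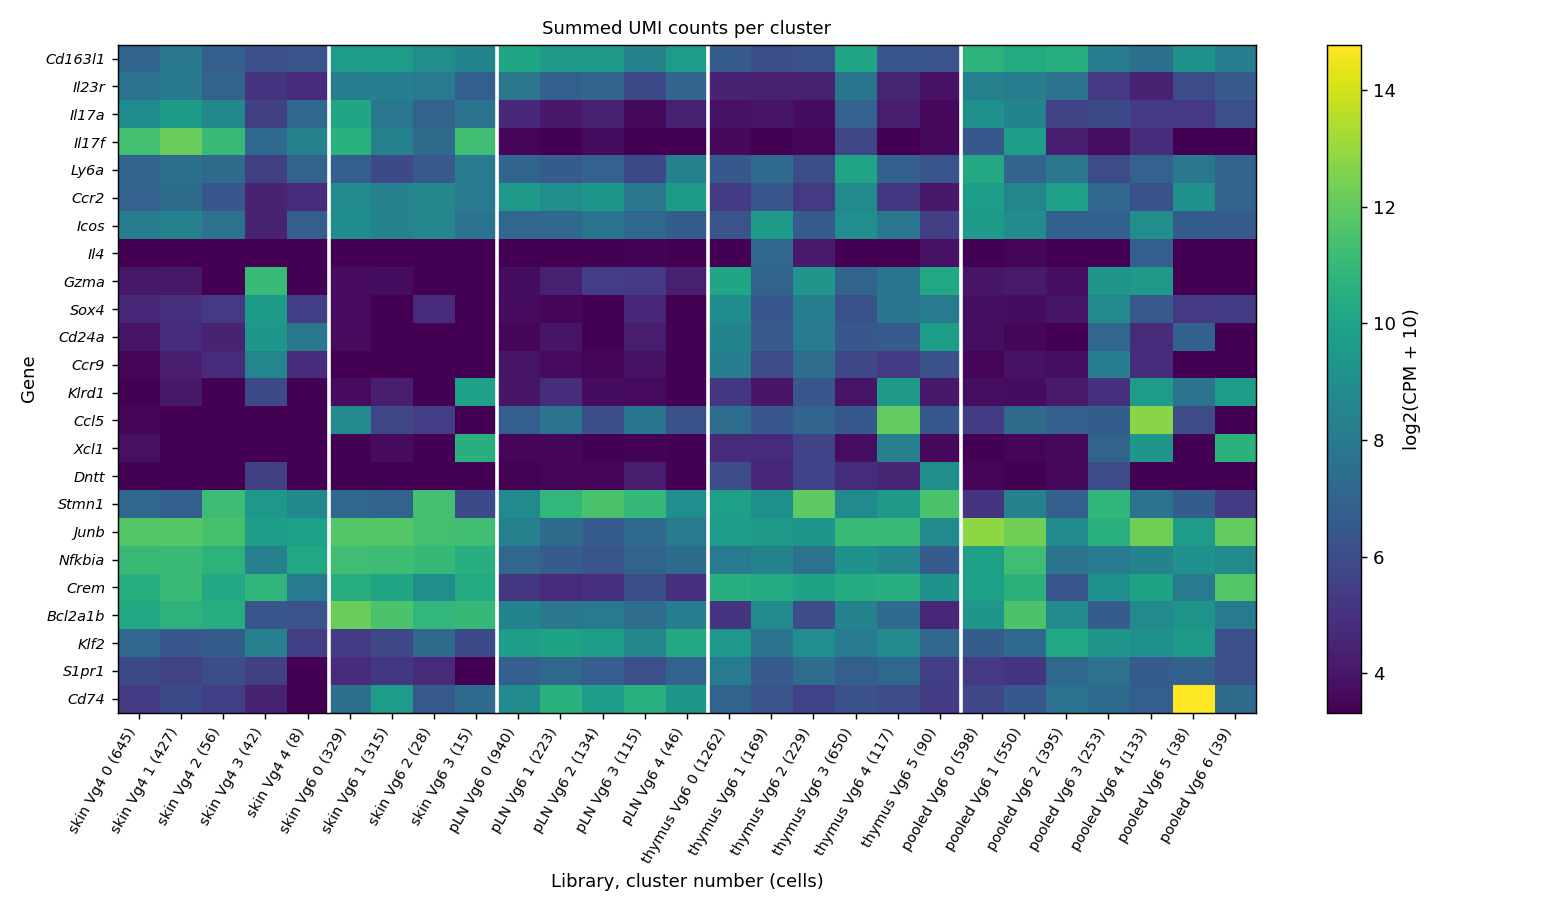
Expression of selected genes (vertical axis) in each cluster of each library (horizontal axis, with the number of cells), as log2 of CPM plus 10 from the UMIs summed over the cluster (colour). Gzma stood at 1093 CPM in the largest thymus cluster and at 2132 CPM in the cluster of 42 skin Vγ4 cells, and Cd74 at 28207 CPM in the myeloid-led cluster of the pool.

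The pooled Vγ6 library asked whether a mixture of these tissues, run together, shows the same profiles. Of 6317 genes, 5348 (84.7%) lay within the range of the skin, pLN and thymus Vγ6 libraries, 695 above and 274 below it. The best mixture was 30.9% skin, 39.9% pLN and 29.2% thymus RNA, with a correlation across genes of 0.929. A cluster of 550 cells followed the contrast of skin against the other tissues (correlation 0.878 across 2779 genes), with Gadd45b at 1253 and Rel at 631 CPM. A cluster of 395 cells followed pLN (0.779), with Klf2 at 1109 CPM. The cycling and the cytotoxic cluster, 253 and 133 cells, followed thymus (0.619 and 0.5002), with Sox4 at 416 and Ccl5 at 6956 CPM. The largest cluster, 598 cells with Il17a at 524 and Ly6a at 1214 CPM, followed none of them closely (0.00759, 0.168 and -0.0411 for skin, pLN and thymus), and by best single profile 385 of its cells fitted thymus, 189 pLN and 24 skin. Neither these correlations nor the best single profile map single cells to tissues. Il17a and Il17f were among the genes used to find the best profile.

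The authors deposited tables for 8 Vγ6 clusters, which were set beside the summed counts. In the authors' deposited table the strongest Skin markers were Furin at 13.3-fold, Bcl2a1b at 13.3-fold, Il17f at 10.9-fold and Bcl2a1d at 10.6-fold. In the same authors' deposited table Thy_4 was led by Ccl5 at 22.7-fold and pLN_2 by Cd74 at 9.97-fold. Of 1562 Skin markers with at least 0.25 natural log units in the authors' deposited table, 1561 had the same direction in the skin library against the other Vγ6 libraries, and of 1080 markers of pLN_1, 1049 did. The tables belong to the same series, so this is no independent evidence. Cluster means in the authors' deposited table correlated with clusters of the present analysis at 0.996 across genes for Skin, 0.998 for pLN_1 and at least 0.985 for the others, taking the best match of each deposited cluster, with genes not being independent replicates. Other pairs reached 0.990, so a value at this level did not single out a cluster, and the cytotoxic skin cluster had a best match of only 0.866.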

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

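The comparison for damaged cells was chosen after the result was seen, and the test of barcodes gathering RNA was written before its own result.

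Some cell barcodes held part of the template-switch oligo sequence (ACATGGG, GTACATG or CATGGGA), and in 3 libraries they were frequent among the barcodes left out. Among these they numbered 87 of 216 (40.3%) in skin Vγ4, 83 of 125 (66.4%) in skin Vγ6 and 21 of 32 (65.6%) in thymus Vγ6, against 0 of 12 in the pooled library. In pLN all 30 were kept, 24 of them in 1 cluster, and in thymus 48 of 69 were kept. Skin Vγ4 and skin Vγ6 shared 13 barcodes, 10 of them with the sequence, skin Vγ4 and thymus shared 13, with 7, and skin Vγ6 and thymus 11, with 7. With pLN, skin Vγ4 shared 11, with 3, thymus 12, with 4, and skin Vγ6 2, with 2. The pool shared 2 to 7 barcodes with each other library, with at most 2 holding the sequence.

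Damaged cells alone could give a high mitochondrial share, but any such cell would carry a random barcode. In skin Vγ4 the sequence was 158 times as frequent over the mitochondrial limit as among kept barcodes (40.3% against 0.255%). These are the same barcodes that raised the question, so this comparison restates it and is no separate test of damage. Barcodes that gather RNA of many cells may be the source: among kept thymus barcodes, 31 of 48 with the sequence (64.6%) mixed genes of the Gzma-rich and IL-17-type clusters, against 13.7% without it, a ratio of 4.70. Leaving these barcodes out moved none of the named gene ratios or list medians.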

How the results depend on the processing

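No paired analysis was possible because each group had 1 library. Values are log2 ratios or list medians, and the cause was not tested unless stated.

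Of the alternatives fixed before the data were seen, 2291 of 2585 gene values stayed, 292 moved and 2 reversed. Of list medians 608 of 704 stayed, 96 moved and 0 reversed, and of counts 72 of 88 stayed and 16 moved. A value was labelled reversed only where the main gene ratio passed the size rule or the main list median was at least 2-fold. Smaller medians that changed sign were labelled moved or stayed. Among the moved ones, the skin over pLN IL-17, circulation, lipid handling and thymocyte medians changed sign. So did the thymus over pLN residency and T cell receptor, the skin over thymus cytotoxic and the skin Vγ4 over Vγ6 chemokine receptor medians. Of the alternatives added after the data were seen, 837 of 1080 gene values stayed, 237 moved and 6 reversed, and 191 of 240 list medians stayed, 46 moved and 3 reversed. Over all called list members, 31 of 5872 values reversed, 26 with the thymus IL-17-type cluster only, 3 with dividing clusters left out by leading genes and 2 with T cell clusters only.

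Reversed values with T cell clusters only were Klrd1 for skin over pLN, -0.36, and Xcl1 for skin Vγ4 over Vγ6, 0.72, which follows from leaving out the clusters that hold these genes. With the thymus IL-17-type cluster only, thymus over pLN reversed for the IL-17 median (0.46), Bcl2 (-0.29), Bcl2a1b (0.36) and Cd163l1 (0.49). Skin over thymus reversed for the IL-17 median (-0.0538), the cell cycle median (0.00762), Ccr6 (-0.0552), Cd163l1 (-0.46) and Rrm2 (0.0119). That cluster was chosen by IL-17-type markers, which raises the IL-17 list with Ccr6 and Cd163l1 by construction. Keeping it alone also leaves out the cycling-named thymus cluster, 229 cells with 19.1% of the UMIs. This lowers Rrm2 and the cell cycle list in thymus by construction. For Bcl2 and Bcl2a1b the cause was not tested.

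With a 100 CPM minimum, higher and lower genes numbered 364 and 554 for skin over pLN, 207 and 185 for thymus over pLN, 319 and 352 for skin over thymus, and 30 and 28 for skin Vγ4 over Vγ6. With no CPM minimum they numbered 1451 higher for skin over pLN, 1784 and 1503 for thymus over pLN, 1311 and 2110 for skin over thymus, and 396 and 348 for skin Vγ4 over Vγ6. The stricter filter gave 259 lower genes for skin Vγ4 over Vγ6. With genes at 2-fold between tissues the thymus share of the pool was 31.8%. At resolution 1.0 the cells outside the T cell names were 0% of skin Vγ4, 4.80% of skin Vγ6, 7.54% of pLN and 15.9% of thymus.

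List medians moved as follows. With no cell filter, for thymus/pLN residency -0.14. With the stricter filter, for skin/pLN lipid 0.61, T cell receptor -0.67, for thymus/pLN IL-17 -1.20, residency -0.0707, cell cycle -1.05, for skin/thymus activation 2.18, residency 2.52, cytotoxic 1.05, lipid -0.75, T cell receptor -0.61, and for Vγ4/Vγ6 IL-17 -0.64, NF-κB -0.56, activation -0.63, residency -0.85, cell cycle 0.73. With T cell clusters only, for thymus/pLN residency -0.0965, cytotoxic 2.15 and for Vγ4/Vγ6 cytotoxic -0.77. With doublet calls left out, for thymus/pLN residency -0.15. With TMM factors, for skin/pLN IL-17 0.45, heat shock 1.45, T cell receptor -0.62, for thymus/pLN heat shock 1.32, residency -0.0594, T cell receptor 0.16, and for skin/thymus immediate early 2.11, heat shock 0.35, T cell receptor -0.66. With median-of-ratios factors, for skin/pLN IL-17 0.45, heat shock 1.45, T cell receptor -0.62, for thymus/pLN residency -0.11, and for skin/thymus IL-17 1.96, immediate early 2.16, heat shock 0.40, activation 1.91, T cell receptor -0.61. With the mean over cells, for skin/pLN IL-17 -0.14, heat shock 1.38, circulation -0.38, T cell receptor -1.10 and for thymus/pLN immediate early 1.27, heat shock 1.34, residency 0.74, circulation 1.48, cytotoxic 2.43, chemokine receptor -2.25, T cell receptor -0.0845. With thinning, for skin/pLN heat shock 1.39, NF-κB 3.63, cytotoxic 1.32, thymocyte -0.18, T cell receptor -1.19, for thymus/pLN immediate early 1.23, residency 0.72, circulation 1.61, interferon 0.39, chemokine receptor -1.38, T cell receptor -0.0755, and for skin/thymus IL-17 1.27, immediate early 1.55, residency 1.16. With mitochondrial, ribosomal and stress genes out of the total, for skin/pLN immediate early 3.15, T cell receptor -0.65 and for thymus/pLN chemokine receptor -1.20, T cell receptor 0.15. With no CPM minimum, for skin/pLN heat shock 0.82, activation 2.78, residency 1.48, cytotoxic 0.60, thymocyte -0.67, T cell receptor -0.70, for thymus/pLN cytotoxic 1.39, lipid 0.31, chemokine receptor -0.71, for skin/thymus activation 1.24, residency 0.62, cytotoxic -1.002, lipid -0.53, chemokine receptor 0.62, and for Vγ4/Vγ6 cytotoxic -0.33, chemokine receptor -0.0990. With a pseudocount of 10 CPM, for skin/pLN NF-κB 3.53, residency 2.09, cytotoxic 1.39, for thymus/pLN heat shock 1.11, NF-κB 1.201, activation 1.94, circulation 1.45, cytotoxic 1.80, chemokine receptor -1.39, thymocyte 2.57, and for skin/thymus IL-17 1.34, residency 1.56, thymocyte -2.30. With dividing clusters left out by leading genes, for skin/pLN IL-17 -0.33, immediate early 2.28, heat shock 1.53, circulation -0.50, cell cycle -1.83, T cell receptor -1.24 and for thymus/pLN IL-17 -1.68, immediate early 1.02, heat shock 1.62, circulation 1.31, cell cycle -0.0887, interferon 0.0339, glycolysis 0.37, lipid 1.12, T cell receptor -0.20. With dividing clusters left out by the marker rule, for skin/pLN T cell receptor -0.67, for thymus/pLN IL-17 -1.02, circulation 1.67, cell cycle -2.29, interferon 0.94, T cell receptor 0.16, and for skin/thymus IL-17 1.41. With the thymus IL-17-type cluster only, for thymus/pLN immediate early 2.20, heat shock 1.56, NF-κB 2.18, residency 1.14, circulation 0.64, cytotoxic 1.96, cell cycle -2.83, interferon 0.35, survival 0.0256, lipid 0.25, chemokine receptor -0.34, thymocyte 2.12, T cell receptor 0.41 and for skin/thymus immediate early 1.09, heat shock -0.29, NF-κB 2.01, residency 1.02, circulation -0.72, cytotoxic 0.82, survival 0.81, lipid -0.62, chemokine receptor 0.97, T cell receptor -1.31. With thymus-like skin Vγ4 cells left out, for Vγ4/Vγ6 thymocyte 0.53.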

Other observations

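The 37 °C, droplet run and index hopping tests were chosen after the result was seen, and the other tests of this part were written before theirs.

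Within thymus the cluster led by IL-17-type genes was set against the whole pLN library. Il22 was 415-fold (177 to 1282), Il17a 12.03-fold (8.42 to 17.6) and Ly6a 10.3-fold (9.27 to 11.6) higher, Il17f 46.6-fold (17.3 to 176), and Cd163l1 1.40-fold (1.32 to 1.49), while Maf was 2.66-fold (2.34 to 3.03) lower. The cluster was chosen by such markers, so the list as a whole is not independent of it. Another thymus cluster, 169 cells, was led by Il4, Icos and Izumo1r. A pLN cluster of 46 cells was led by the interferon genes Isg15, Ifit1 and Ifit3. Killer-type genes marked 15 skin Vγ6 cells, with Xcl1 at 1494 CPM, and 39 pooled cells, with Xcl1 at 1611 CPM. In the pool 83 genes had their whole interval above 2 times the highest single-tissue value. Among them were Spry2 at 175 CPM against at most 27.7 and BC018473 at 151 CPM against at most 5.04. Wfdc17, a leading gene of the myeloid-led cluster of the pool, was also among them at 125 CPM. Most of those with the highest ratios were predicted genes or ribosomal pseudogenes. Examples were Gm10269 at 966 CPM against at most 146 and Rps18-ps3 at 2102 against at most 351, and the cause was not tested. Another 15 had their whole interval below 0.5 times the lowest, such as mt-Atp8 at 121 CPM.

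Stress-response genes were higher in skin than in pLN, with a median log2 ratio of 2.73 over 50 immediate early, heat shock and NF-κB genes. Thinning, which left out the 125 skin Vγ6 cells below 800 UMIs, gave 2.75, so those shallow cells alone did not account for the difference. A random draw of UMIs keeps each cell's gene shares on average. Faulty barcodes at or above that depth stayed in and were therefore not tested. The droplet run is argued against by 2.05 between skin-like and pLN-like cells within the pool. However, the assigning genes may vary together with these lists. Incubation at 37 °C could contribute, because thymus, also incubated, stood 1.47 over pLN, but tissue and incubation differed together and the question stays open. Crem and Vps37b might be low in 1 lymph node preparation only. Together they had 158 CPM in the pLN-like pooled cluster against 57.0 in the pLN library, 2.76-fold (2.12 to 3.57), between the bounds set beforehand. The 663 pooled cells that fitted the pLN profile best held Crem at 258 and Vps37b at 412 CPM. In the pLN library these were at 31.8 and 25.2 CPM. The reading therefore depends on which pooled cells are taken as pLN-like, and the question stays open. A true tissue difference stays possible and was not tested.

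The 42 thymus-like skin Vγ4 cells had Gzma at 2132 CPM against 5.95 in the other cells, and Il17f at 141 against 3231, but 2.14 in the thymus cluster. Thymus cells carried into the sort or library may explain them: on a scale from 0 for the thymus cluster to 1 for other skin cells, 34 stress genes had a median position of 0.0541 (quartiles -0.0299 to 0.213), though their Il17f above the thymus level goes against plain carry-over unless free RNA of skin cells added it, which was not tested, and a resident thymus-like population stays open. Index hopping is argued against, with 0 of 42 barcodes (0%, up to 8.41%) found in thymus. For 19 thymus-like pLN cells the scale ran from 0 for other pLN cells to 1 for thymus, and 15 genes gave 0.578 (quartiles 0.283 to 0.759), which leaves carry-over open. A first run with a 100 CPM minimum gave 0.0606 over 30 genes and 0.465 over 5, and the change of minimum and reading rule after it turned the pLN verdict from excluded to open.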
